A study of Oryza sativa with 3 samples.

How the data were processed

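Total RNA from leaf of transgenic line 22, transgenic line 32 and wild-type rice was labelled with Cy3 and hybridised to 1 array each, per the labels' protocols. Per the labels, plants grew in 1-L pots under 16 h light at 30 and 20 degrees Celsius by day and night, without treatment, and 0.5 ug RNA was labelled. The series' design text states 3 biological replicates per line; the labels do not state whether these were pooled on the single array of each group. All 3 arrays lay on 1 slide, at positions 1, 4 and 2, so no slide or scan batch separates the groups.

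The deposited intensity values are Agilent scanner output: a background-corrected and detrended signal with its error, the mean signal and the local background of each spot. The deposited spot flags mark other properties, such as a spot well above background, saturated or an outlier. Feature Extraction 9.0 made them, per the submitters' processing notes, while the protocol number 107 and grid placement 10.5.1.1 stand in the files per the file headers. The array design is number 015241 per the file headers, with probe positions on rice build IRGSP 5. The authors' deposited value table holds log2 values that are scaled to each array's 75th percentile and centred per probe. Their differences between arrays matched those of the scanner signals, with slopes from 0.998 to 0.999 and r from 0.998 to 0.999 across 27695 spots. The level on which each probe was centred stays unknown: 2 of 3 values were equal and opposite within 0.0001 in 63.4% of 42474 probes. The table's column medians were 0.037 for line 22, -0.0017 for line 32 and -0.0014 for wild type.

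The main values were log2 of the processed signal minus each array's 75th percentile over the 43734 gene spots. Control spots were left out, as were 54, 26 and 62 outlier-marked spots in line 22, line 32 and wild type. Spots of 1 probe sequence were averaged, giving 37955 sequences. A gene took the value of its brightest probe over all arrays, which gave 29068 genes or transcripts, 23791 of them named by locus. Median signals were 85.3, 93.6 and 107 in line 22, line 32 and wild type, with a scanner error of 10.1%, 10.0% and 10.0%. Duplicate spots of a probe scattered with an SD of the log2 ratio of 0.144 for line 22 against wild type, 0.115 for line 32 against wild type and 0.146 between the lines. Of 3156 RefSeq accessions in the files, 0 were found in the reference table, so genes keep the locus names and descriptions of the files.

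The comparisons were each line against wild type and line 22 against line 32. With 1 array per group no test, p-value or error across replicates was possible; a gene was counted where it differed at least 2-fold. A gene entered a comparison if it was well above background on at least 1 of its arrays. Where only 1 array measured it, the bright array's value was set against the higher of the dim spot's own signal and the lowest signal well above background on the dim array, as a bound. Gene lists were written before the data were examined, from locus names and words of the gene descriptions; members whose descriptions matched by mistake were removed after the descriptions were seen. A list's median was placed among 10000 random lists of equal size, matched in 20 bins of mean signal, for lists with at least 4 measured genes. This percentile describes these arrays and is not a test of the conditions. Of 37 lists so placed, 10 in line 22, 12 in line 32 and 11 between the lines lay outside the central 95%. By chance 1.85 would, if genes of a list varied independently of each other, as the random lists assume. Whether they do was not tested, and the simulated data below also used independent scatter.

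Genes named in the text follow a rule fixed before the data were examined, over genes with a functional description. It takes up to 12 higher and 12 lower in both lines, 6 higher and 6 lower per comparison, 3 bounds per direction, up to 4 members of each list and all ASR genes. Genes outside it are said to be chosen after their values were seen. Arrays sharing 1 wild type were simulated 100 times without effects, with scatter per signal bin from line 22 minus line 32.

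The scripts were tested on simulated data with 200 changed genes, in the signal range of the real arrays and with the scatter between the transgenic arrays, which includes any real difference between the lines. For line 22 against wild type, with 19998 genes in the step, 50 of 50 genes put in at 4-fold were called, 47 of 49 at 3-fold, 25 of 50 at 2-fold and 6 of 50 at 1.5-fold; 792 of 19780 unchanged genes passed 2-fold. For line 32 against wild type, with 19958 genes, the numbers were 50 of 50, 49 of 49, 30 of 50 and 4 of 50, and 807 of 19740 unchanged genes passed. A list of 19 genes shifted by 0.3 for line 22 was found with a median of 0.30, above all random lists, and 2 of 36 other lists lay outside the central 95%. The limma step on 20331 simulated genes gave the right sign to 99 of 99 genes changed 3- or 4-fold in both lines and 0 genes with an adjusted p under 0.05.

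Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring and cyclic loess; the mean over a gene's probes; genes well above background on every array compared, or all genes; outlier-marked spots kept; the authors' values; 1.5-fold and 3-fold thresholds; a difference over 1.96 scanner errors; and limma with the lines as samples of 1 transgenic group and Benjamini-Hochberg adjustment. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 were used. Spots annotated to more than 1 gene (29 sequences) kept the first gene identifier.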

Results

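Gene expression was measured in leaves of rice that carried a barley ASR gene (abscisic acid, stress and ripening) and in leaves of the untransformed cultivar, Tainung 67. A pair of transgenic lines, line 22 and line 32, which the series describes as unlike in the level of their transgene, stood beside wild type. No stress was applied, so the comparisons ask which transcripts differ in unstressed leaf. Each line and wild type had 1 single-colour array of 60-base probes, so there are no replicate arrays and no replicate check of any difference, and the number of arrays limits the precision. Between 29087 and 29171 of the 43734 gene spots, or 66.5% to 66.7%, were well above background on each array, and none was saturated. Differences below are in log2 units, a line minus wild type unless stated otherwise. A difference is called "at least N-fold" where 1 of the arrays did not measure the gene well above background.

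Of rice's own ASR genes, proteins linked to abscisic acid and water stress, none was counted as 2-fold different from wild type in either line. All 6 members on the array were measured on at least 1 array, and the family's median difference was 0.06 in line 22 and 0.13 in line 32 (0.056 after normexp background correction). Os11g0167800, Os01g0963600 and Os04g0423400 had the strongest scaled signals of the family in wild type, at 7.11, 6.30 and 3.09. Their differences in line 22 were 0.17, 0.17 and 0.28, and in line 32 they were 0.10, 0.02 and 0.15, of which the value of Os01g0963600 in line 32 became negative (-0.04) at its lowest among the scalings tried. Os02g0543000 lay at -0.05 in line 22 and -0.06 in line 32. The dim gene Os01g0959200 was at -0.27 in line 22 and 0.39 in line 32, and the line 22 value turned to 0.06 after another background correction. Its neighbour Os01g0959100 was not well above background in line 22 and had a difference of 0.26 in line 32. In line 22 only a bound was thus available for it, which cannot exclude a 2-fold difference. No probe was identified with the barley transgene, so its own level was not analysed here.

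The described genes farthest below wild type in both transgenic lines were of mixed kinds. A gene similar to a 4,5-DOPA dioxygenase, Os01g0878900, stood lowest of the described genes measured on all arrays, at -4.12 in line 22 and -4.66 in line 32. An isoflavone reductase homologue, Os01g0106300, had differences of -3.25 and -4.20, a mannose-binding lectin gene, Os03g0399800, -2.53 and -4.53, and a sulfotransferase gene, Os09g0555150, -2.50 and -2.84. A gene similar to flavonoid 3'-monooxygenase, Os10g0320100, had -2.14 and -2.31, and a UDP-glucosyltransferase family gene, Os06g0289900, -1.95 and -2.44. A laccase-7-like gene, Os01g0850700, of the enzyme family that polymerises lignin, was at -1.99 and -2.23, and its further probes averaged -1.73 and -2.11. The class III peroxidase Os05g0135500 lay at -1.81 and -2.67, and a monosaccharide transporter, Os04g0454200, at -1.63 and -2.32.

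Genes higher in both lines included single receptor kinase and NB-ARC genes, but the median of these families lay within the range of random lists in each line: of 138 members measured in both comparisons, 3 were at least 2-fold higher and 2 lower in both lines. An NB-ARC gene, Os06g0163900, of the domain found in plant resistance proteins, was 2.37 above wild type in line 22 and 2.08 in line 32. A pair of receptor-like kinases, Os06g0130100 and Os11g0208800, had differences of 1.64 and 1.17 in line 22 and of 1.15 and 1.44 in line 32. The transcription factor MADS27, Os02g0579600, was 2.84-fold and 3.54-fold higher, and log2 differences were 2.09 and 1.87 for a cytochrome P450, Os07g0635300, and 1.08 and 1.17 for an Exo70 exocyst gene, Os05g0369900. A gene similar to WRKY transcription factor 12, Os01g0624700, stood at 1.00 and 1.30, but its further probe, well above background on 1 array, had 0.16 in line 22 and 1.36 in line 32. Os10g0432200, similar to the 68 kDa protein HP68, was not well above background in wild type and was at least 64.3-fold higher in line 22 and at least 16.8-fold higher in line 32. Os10g0419400, similar to SIPL, was at least 49.0-fold and 57.3-fold higher. Sizes of dim genes depend on the background correction: after normexp the log2 bounds of Os10g0432200 went from 6.01 and 4.07 to 3.22 and 1.59, and those of Os10g0419400 from 5.61 and 5.84 to 3.22 and 3.33. Of the 10 genes named because they stood highest in both lines, 1 was still 2-fold higher in both after normexp, the aspartic peptidase gene Os08g0441700 at 1.34 and 1.11, whereas 10 of the 12 named as lowest were still 2-fold lower.

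Across the array, 220 of 19324 genes differed at least 2-fold in the same direction in both lines, 84 of them higher and 136 lower. Of these 19324 genes, 214 were higher and 286 lower in line 22, and 119 and 307 in line 32; unrelated calls of those numbers would share 1.32 higher and 4.54 lower genes. Both comparisons use the same wild-type array, and simulated unchanged leaves set against 1 shared wild type had on average 68.3 such genes (49 to 92), counting only genes measured on all arrays. The real arrays had 83, inside that range, 24 of them higher and 59 lower. The simulated scatter came from line 22 minus line 32, includes any real difference between them and favours no direction. The simulation therefore cannot decide whether the shared count exceeds what arises with no effect. The changes of the lines correlated across 18435 genes, which are not independent replicates, with Pearson r 0.61 and Spearman's rho 0.50. The simulated r was 0.50 (0.45 to 0.55), and the covariance was 0.050 beside a simulated 0.041 (0.036 to 0.046). Both real values lay above all 100 simulations, in which the scatter of the wild-type array was taken from the transgenic arrays. Only 41 genes passed 2-fold in both lines after normexp background correction, and limma, with the lines taken as samples of 1 group, called 0 genes and had 1109 with unadjusted p under 0.05.

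**Figure D1:**
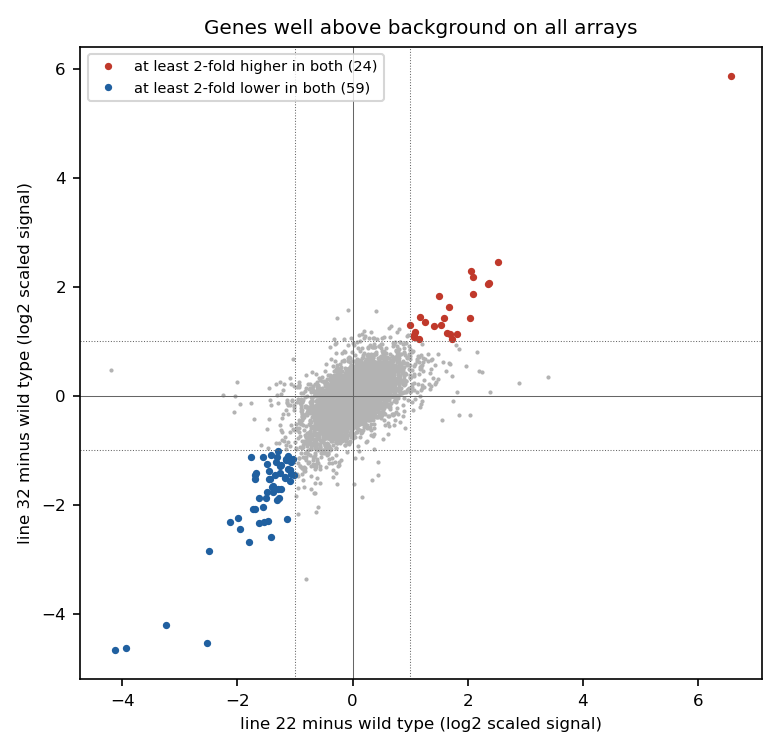
Each point is 1 of the 18435 genes measured well above background on all arrays, with its log2 difference from wild type in line 22 (x axis) and line 32 (y axis). Dotted lines mark 2-fold; 24 genes lie beyond it upwards and 59 downwards in both lines.

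Flavonoid and phenylpropanoid genes were shifted down as a group in both lines. Of 48 measured members in line 22, 5 were at least 2-fold lower and 2 at least 2-fold higher; of 43 in line 32, 10 were lower and 0 higher. Both chalcone synthase genes named by the rule, the entry enzyme of flavonoid synthesis, were among them: Os11g0530600 at -1.49 and -1.76, and Os07g0214900 at -1.68 and -1.42. Phenylalanine ammonia-lyase Os04g0518400, which opens the phenylpropanoid pathway, had -1.33 and -1.21, and the chalcone isomerase Os12g0115700 had -1.25 and -1.71; after normexp these went to -0.39 and -0.59 and to -0.54 and -0.85, none of them 2-fold. The list's median was -0.14 in line 22 and -0.12 in line 32, below all 10000 random lists of equal size and signal in each line and under every scaling tried. With dim probes kept, the line 22 median turned to 0.058, at percentile 16.5, and that of line 32 was -0.05, at percentile 0.76.

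Genes of cellulose synthesis and the secondary wall were lower too, and further below wild type in line 32. Their median was -0.53 in line 32, where 5 of 18 measured members were at least 2-fold lower, and -0.23 in line 22, where 2 of 19 were lower and 1 was higher. After normexp correction the medians were -0.17 in line 32 and 0.00 in line 22, the latter at percentile 6.42, inside the central 95% of random lists. That 0.00 can be a bound set to 0, so it does not show that the shift vanished. With dim probes kept they were -0.02 in line 32, at percentile 23.3, and -0.06 in line 22, at percentile 0.03. Os10g0467800 and Os01g0750300, both placed in this list by their locus, were at -0.95 and -0.66 in line 22 and at -2.16 and -1.35 in line 32; after normexp they were at -0.56 and -0.14 and at -1.27 and -0.55. A gene similar to the cellulose synthase CesA7, Os07g0252400, had -0.46 and -0.89. Expansins and xyloglucan enzymes had medians of -0.12 and -0.13, which after normexp became 0.015 and -0.029, within the range of random lists, with 1 of 19 members at least 2-fold lower in line 22 and 0 of 20 in line 32.

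Neighbouring genes of the Tify family, which holds the JAZ repressors of jasmonate signalling, went both ways. Os03g0181100 was at -1.73 and -2.07, whereas Os03g0180900 was at 1.42 and 1.28 (1.00 and 0.77 after normexp). Of 29 measured genes of jasmonate synthesis and repression, 5 in line 22 and 6 in line 32 were at least 2-fold lower and 1 was higher in each. The list's median was -0.02 in line 22 and -0.11 in line 32 (-0.044 after normexp).

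Glutathione transferases, which conjugate toxic and oxidised compounds, sat slightly above wild type as a group. Their median was 0.14 in line 22 and 0.10 in line 32 (0.065 after normexp), above 99.98% of random lists in line 32 and above all in line 22, although 0 of 49 members were 2-fold higher and 1 was 2-fold lower in each line. Os10g0368100 was at 0.71 and 0.91, and Os10g0528900 at -0.88 and -1.33 (-0.44 and -0.74 after normexp). Light harvesting and photosystem genes had medians of 0.18 and 0.12, but these became 0.0087 and -0.038 after quantile normalization, and 1 of 43 members, the PsbQ-like Os02g0578400, was at least 2-fold lower in each line, but at -0.57 and -0.94 after normexp. Pathogenesis-related genes had more members 2-fold higher than lower, 6 against 1 in line 22 and 5 against 1 in line 32, while their medians were -0.08 and -0.06. The line 22 median turned to 0.0064 after normexp, still at percentile 0.96 of random lists, and to 0.13 with dim probes kept, at percentile 59.3. The thaumatin-like Os03g0243900 had -1.39 and -1.66 (-0.93 and -1.20 after normexp).

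**Figure D2:**
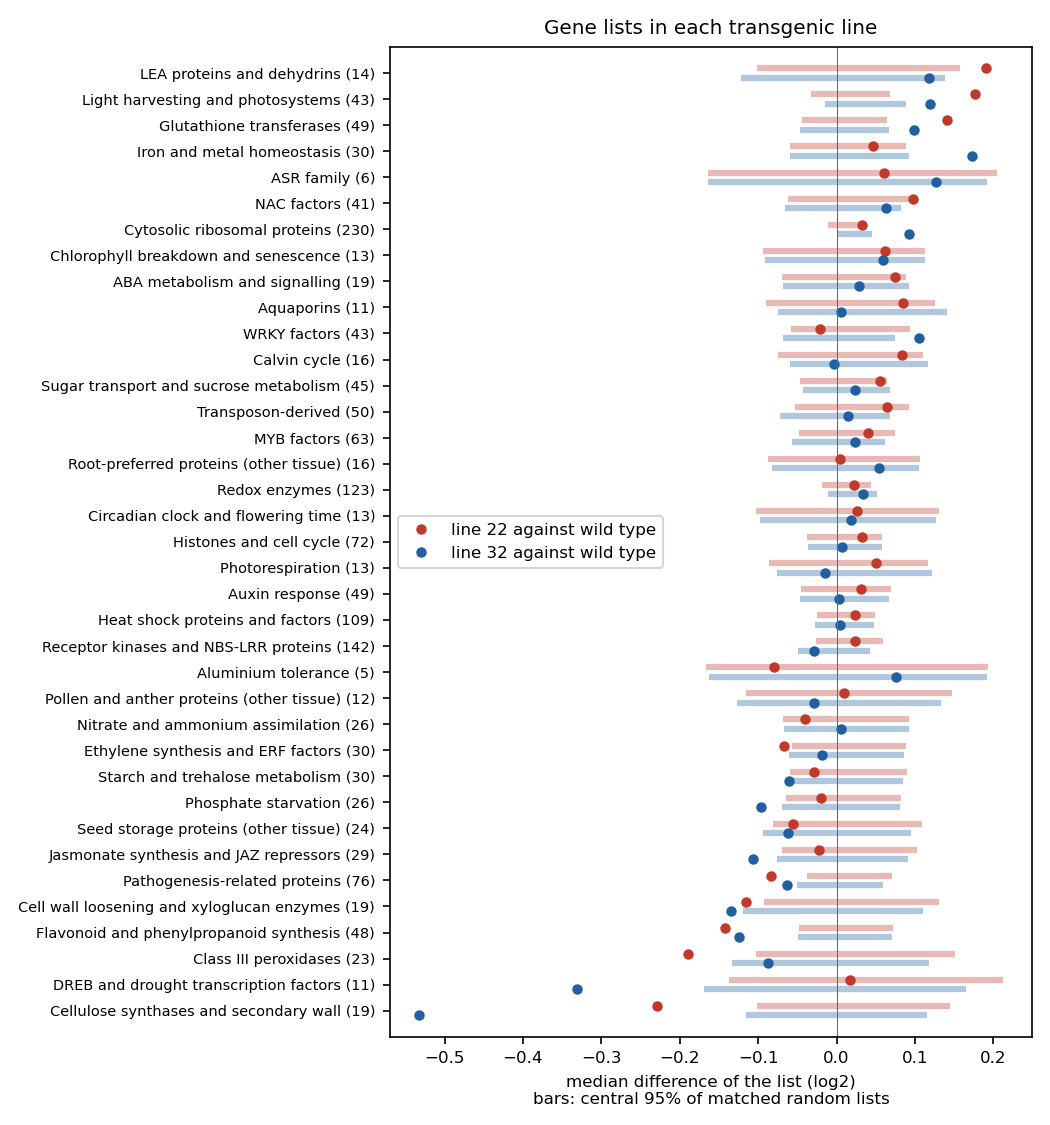
Points give the median log2 difference from wild type of each gene list with at least 4 measured genes, in line 22 (red) and line 32 (blue). The number of measured genes for line 22 stands in brackets. Bars span the central 95% of matched random lists. Secondary wall genes are lowest of the lists drawn, at -0.23 and -0.53. The light harvesting medians of 0.18 and 0.12 become 0.0087 and -0.038 under quantile normalization. Under normexp the line 22 medians of secondary wall genes and class III peroxidases become 0.00, at percentiles 6.42 and 1.005 of random lists. A median of 0.00 can be a bound set to 0.

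In line 22 against wild type, the highest transcripts included lipid transfer, glycosyltransferase and invertase genes, and peroxidase genes were among the lowest. A lipid transfer protein gene, Os01g0822900, was at 2.38 in line 22 and 0.08 in line 32, and a glycosyltransferase of family 47, Os03g0684500, at 2.24 and 0.45. The cell wall invertase Os08g0158600, which splits sucrose outside the cell, was at 2.03 in line 22. OsNramp1, Os07g0258400, a metal transporter, had 1.39 (0.74 after normexp, no longer 2-fold). The peroxidase gene Os07g0677200 was not well above background in line 22 and was at least 25.1-fold lower there, while line 32 values lay between -0.04 and 0.0046 over the scalings tried; its neighbour Os07g0677100 was at least 5.90-fold lower. After normexp the log2 bound of Os07g0677200 went from -4.65 to -2.32 and that of Os07g0677100 from -2.56 to -0.52, no longer 2-fold.

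Late embryogenesis abundant proteins and dehydrins, which protect drying cells, had a median of 0.19 in line 22 (0.12 in line 32). In line 22 this was above 99.1% of random lists, but at percentile 85.3 with dim probes kept, inside the central 95%. There 1 of 14 measured members was at least 2-fold higher in the main setting. Dehydrin RAB 16B, Os11g0454200, was at 0.73 (0.33 after normexp). Heat shock genes were centred at 0.02, with 2 of 109 members 2-fold higher and 1 lower, the small heat shock protein gene Os02g0217900 at -2.01. Abscisic acid genes had 0 of 19 members 2-fold away from wild type, and the kinase SAPK9, Os12g0586100, was at 0.40. Aquaporins had 0 of 11 beyond 2-fold. Class III peroxidases had a median of -0.19, which became 0.18 with dim probes kept. After normexp it was 0.00, which can be a bound set to 0. At least 2-fold lower were 3 of 23 members, among them Os01g0294700 at -1.46. These 3 were also 2-fold lower in line 32, where Os07g0677200 was near wild type, so that gene is not 1 of them.

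In total 795 of 19725 genes differed at least 2-fold between line 22 and wild type, 509 higher and 286 lower. Bounds made up 399 of the higher and 168 of the lower genes; among genes measured on both arrays the numbers were 110 higher and 118 lower. Quantile normalization gave 421 higher and 365 lower, and normexp 95 genes in all. Line 22's array had spike-in and gene-spot coefficients of variation of 10.1% and 8.54%, outside the scanner software's accepted range. Simulated arrays with no real difference, whose scatter came from line 22 minus line 32, gave 792 such genes of 19780. The transgenic arrays set against each other gave fewer, 656 of 19710, although the scatter was taken from them. The simulation thus counted more genes than its own source. Its scatter also includes any real difference between the lines, so it cannot decide whether the count separates line 22 from wild type.

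**Figure D3:**
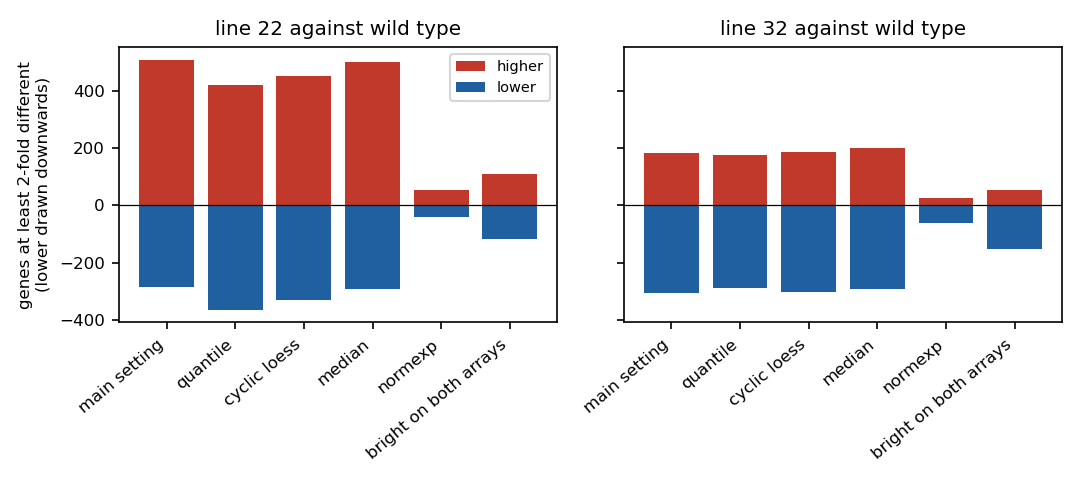
Bars count the genes at least 2-fold higher (red, upwards) and lower (blue, downwards) than wild type in line 22 (left) and line 32 (right). The settings drawn are the main one, quantile, cyclic loess, median centring, normexp and genes well above background on both arrays. The setting with dim probes kept is not drawn: it gave 1631 higher to 587 lower in line 22 and 623 to 733 in line 32. The split in line 22 is 509 to 286 in the main setting, 421 to 365 after quantile normalization and 110 to 118 among genes measured on both arrays.

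Line 32 had more genes below than above wild type, and the drought-linked factor DREB1B was among the low ones. DREB1B, Os09g0522000, an activator of cold and drought genes, was at -1.85 in line 32 and 0.17 in line 22, and its further probe had -1.92 and 0.06. Of 11 measured DREB and drought factors, 2 were at least 2-fold lower and 0 higher in line 32, with a median of -0.33, at percentile 0.07 of random lists (-0.14 after normexp, at percentile 0.31). The counts were equal in line 22, 2 lower and 0 higher, with 1 gene lower in both lines; the line 22 median was 0.02 (0.00 at its lowest among the scalings) and the mean -0.44. The class I heat shock gene Os01g0136100 lay at -1.69 in line 32 (-0.89 after normexp) and -0.95 in line 22. Heat shock genes as a list lay within the range of random lists in line 32, with 0 members 2-fold higher, 2 lower and a median at percentile 34.6. A lipid transfer and seed storage domain gene, Os03g0251000, was at -2.29 in line 32 and -1.47 in line 22, and a peptidase A1 gene, Os06g0118700, at -2.26 and -1.13 (-0.96 in line 22 after normexp). A pectin methylesterase gene, Os01g0312500, was at -2.51 in line 32 (-1.08 after normexp) and at least 7.70-fold lower in line 22, where it was not well above background and the log2 bound went from -2.94 to -0.95 after normexp, no longer 2-fold.

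Genes above wild type in line 32 were fewer. An epsin-like gene, Os11g0244600, was at 1.24 in line 32 and 0.63 in line 22, a class II aminotransferase domain gene, Os10g0430600, at 1.17 and 0.77, and the transcription factor OSMYB4, Os01g0695900, at 1.08 and 0.64, where its further probe had 0.36 in line 32. After normexp they were at 0.85, 0.42 and 0.29 in line 32, no longer 2-fold. WRKY factors had a median of 0.11 (0.057 after normexp), above 99.6% of random lists, with 1 of 40 members 2-fold higher. Class III peroxidases had 5 of 25 members 2-fold lower and 1 higher, and 3 of the lower ones were also lower in line 22. Their median in line 32 was -0.09, at percentile 9.23, inside the central 95% of random lists. A metallothionein gene, Os05g0202800, was at -1.14 although the iron and metal list as a whole had a median of 0.17 (0.097 after normexp).

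Altogether 490 of 19587 genes differed at least 2-fold, 183 higher and 307 lower. Of these, 130 higher and 155 lower genes were bounds; 53 higher and 152 lower genes were measured on both arrays, and 87 genes passed after normexp. Simulated unchanged arrays, with scatter again from line 22 minus line 32, gave 807 of 19740. Duplicate spots scattered more between the lines (SD 0.146) than for line 32 against wild type (0.115). The simulated scatter can thus be too wide here and cannot decide whether the count separates line 32 from wild type.

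The lines differed from each other most in secondary wall, WRKY and ribosomal protein genes, ranked by the place of a list's median among random lists. The series describes the lines as unlike in the level of their transgene, which was not analysed here. Secondary wall genes were higher in line 22 than in line 32, with a median of 0.34, above all random lists, and 3 of 18 members at least 2-fold higher. WRKY factors were lower in line 22, with a median of -0.18 (-0.042 after normexp), below all random lists under both, and 32 of 43 members below 0. WRKY76, Os09g0417600, was at -0.57 (-0.04 after normexp), but its further probe differed from wild type by 0.02 in line 22 and -0.50 in line 32, the other way round. Cytosolic ribosomal protein genes had a median of -0.05, with 153 of 230 members below 0. DREB1B was 2.02 higher in line 22 and the cupredoxin gene Os06g0218600 1.89 higher. Late embryogenesis abundant proteins had a median of 0.20, above 99.2% of random lists, with 0 of 14 members beyond 2-fold. That median was 0.16 after normexp, at percentile 96.99, and 0.19 with dim probes kept, at percentile 81.71. Both percentiles lay inside the central range of random lists. Auxin response genes had a median of 0.13 (0.078 after normexp), with 0 of 49 members beyond 2-fold. A mitochondrial transcription termination factor gene, Os03g0360600, was at -2.26, and the formate dehydrogenase gene Os06g0486800 at -1.62; against wild type in line 22 the latter was at -1.76 and its further probe at -0.07. A vegetative storage protein gene, Os05g0189300, was at least 23.8-fold higher in line 22, and a major facilitator antiporter gene, Os12g0132500, at least 10.3-fold lower. After normexp these log2 bounds went from 4.57 to 1.66 and from -3.36 to -0.86, the latter no longer 2-fold.

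In this comparison 656 of 19710 genes differed at least 2-fold, 463 higher in line 22 and 193 lower. Among genes measured on both arrays there were 111 higher and 49 lower, quantile normalization gave 398 and 285, and normexp gave 23 of each.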

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

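A gene named by the rule is given here where it was well above background on all arrays, so that no bound is included, and both lines lay on opposite sides of wild type, each by more than a limit set from the scatter of duplicate spots, 0.28 in line 22 and 0.23 in line 32, which covers the noise of spots and not that between plants. This limit was not among the choices fixed before the data were examined. The difference between the lines was not tested, since each is 1 array.

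The cell wall invertase gene Os08g0158600 was at 2.03 in line 22 and -0.36 in line 32, but after normexp the line 32 value was -0.09, inside the limit. The small heat shock protein gene Os02g0217900 was at -2.01 in line 22 and 0.25 in line 32. The cupredoxin gene Os06g0218600 was at 0.44 in line 22 and -1.45 in line 32, and its further probe had 0.42 and -1.32.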

How the results depend on the processing

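No paired analysis was possible because the groups share only replicate number 1. The lists as first written were an alternative chosen after seeing the data; the others were planned. Quantile normalization, median centring, cyclic loess, the mean over probes, outlier-marked spots kept and the authors' values left every count within 1.5 times its main value: 765 to 815 genes for line 22 (main 795), 463 to 532 for line 32 (490), 615 to 683 between the lines (656) and 212 to 235 in both lines (220). The lists outside the central 95% in both lines numbered 5 to 7 there and with the lists as first written (main 6).

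Normexp gave 95, 87, 46 and 41 genes in the same order; its added offset shrinks differences of dim genes. Genes well above background on every array compared numbered 228, 205, 160 and 83, mainly since bounds were left out. For line 22, 399 higher and 168 lower of the 795 genes were bounds, while the genes tested fell only from 19725 to 18575. With all genes kept there were 2218, 1356, 2046 and 558, and r was 0.49; more genes were tested. Then 2 lists stood out, 2 higher and 0 lower, and 1 of them was among the main 6, so no list was lower in both lines. After normexp 7 lists stood out, 4 of them among the main 6. A 1.5-fold threshold gave 1667, 1297, 1427 and 585 genes and a 3-fold one 298, 154, 279 and 68, by construction. Requiring in addition a difference beyond the combined scanner error left 503 for line 22 and 394 between the lines. Limma called 0 genes, and 1109 had unadjusted p under 0.05; its spread rests on 1 residual degree of freedom, and it called 0 in simulated data with known changes too.

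Higher against lower genes were 509 to 286 in line 22 and 463 to 193 between the lines, but 421 to 365 and 398 to 285 after quantile normalization, and 23 to 23 between the lines after normexp. In both lines together, 84 to 136 became 20 to 21 after normexp.

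Of 5324 values of named genes, 4782 stayed within the spread of duplicate spots and 542 moved, 354 of them after normexp. Beyond that spread 0 changed sign. Of 999 list medians, 804 stayed, 182 moved and 13 turned, all 13 from lists outside the central 95% in the main setting. Lists inside it changed sign too but were counted as moved or stayed, such as starch genes in line 22 (-0.028 to 0.024 after normexp). Of these 13, the medians that turned after normexp were cell wall loosening (0.015), pathogenesis-related (0.0064) and ethylene genes (0.0094) in line 22 and iron genes (0.0068) between the lines. With dim probes kept, those of the 13 that turned in line 22 were cell wall loosening (0.18), class III peroxidases (0.18), pathogenesis-related (0.13), ethylene (0.015) and flavonoid genes (0.058). Between the lines they were ethylene (0.019) and iron genes (0.012). Light harvesting turned after quantile normalization in line 32 (-0.038) and after median centring between the lines (-0.0088). In line 22 the median over all genes itself rose from 0.013 to 0.040 after normexp and to 0.078 with dim probes kept. A turn of sign is thus not always a turn against other genes. After normexp, pathogenesis-related genes in line 22 stayed at percentile 0.96 of random lists, while cell wall loosening was at 13.1 and ethylene at 22.3. With dim probes kept, ethylene was at 2.15 in line 22 and at 3.31 between the lines, and the other turned lists lay between 16.5 and 59.3. The cause was not tested further. Between 66.5% and 66.7% of spots were well above background, which limits what dim genes can show.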

Other observations

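Of the tests below, the draws over chromosomes and the tests of further probes for the chromosome 7 and the wall genes were chosen only after the result was seen; the others were set before. Cytosolic ribosomal protein genes were above wild type in line 32, with a median of 0.09, above all random lists, and 184 of 230 members above 0; in line 22 the median was 0.03. The 40S gene Os04g0502300 was at 0.57 in line 22 and 0.59 in line 32. Phosphate starvation genes had a median of -0.10 in line 32 and -0.02 in line 22, the latter 0.0050 at its highest among the scalings. Of 26 members 0 were beyond 2-fold, and Os02g0514500, a glycerophosphodiester phosphodiesterase, was at -0.84 in line 32. Starch and trehalose genes had a median of -0.06 in line 32, where the beta-amylase gene Os07g0543300 was at -1.26 (-0.51 after normexp). That median was -0.11 after normexp but 0.0185 with dim probes kept, at percentile 73.9. Circadian clock genes had 0 of 13 members beyond 2-fold in either line, and the TOC1-like Os11g0157600 was at 0.36 and 0.26.

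Several genes of unknown function, chosen after their values were seen, were far above wild type in both lines and near background in wild type. Os07g0511400 was at least 446-fold higher in line 22 and 384-fold in line 32, Os07g0122000 at least 81.2-fold and 79.5-fold, and Os11g0123600 at least 66.1-fold and 62.9-fold. After normexp the log2 bounds in line 22 went from 8.80 to 5.91 for Os07g0511400, from 6.34 to 3.50 for Os07g0122000 and from 6.05 to 3.52 for Os11g0123600. The neighbours Os06g0163900 and Os06g0163701 had near-equal differences, 2.37 and 2.35 in line 22 and 2.08 and 2.06 in line 32. The microRNA entry osa-miR439j was 1.32 above wild type in line 22 and at least 2.61-fold below it in line 32, the only gene with 2-fold calls of opposite direction in the lines; after normexp it was at 0.50 and -0.19.

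Genes higher in both lines gathered on chromosome 7, with 18 of 84, where 7.08 were drawn on average; counted as loci at least 50000 bases apart, 13 stood against 6.97. An excess as large on some chromosome arose in 1300 of 10000 draws of genes of equal signal, so chance placement stays open. The other chromosome 7 genes argue against an extra copy of chromosome 7 in both lines: their median was at most 0.015, where an extra copy would give 0.58. Sequence variants under single probes, between the lines and the wild-type plants used, may account for part of the pattern and cannot be told apart from expression: a further probe detected on at least 1 array was also 2-fold higher in both lines for 5 of 8 genes, and only 2 such genes lie on chromosome 7, both higher. An effect of the transgene, or of where it was inserted, stays open and untested.

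Of the 795 genes 2-fold different in line 22, 509 were higher, and 399 of these were bounds. A raised floor of dim scaled signals on line 22's array is consistent with this: 153 negative control spots, scaled like the gene spots, lay 0.22 higher (bootstrap error 0.013) than on the wild-type array, and 0.041 higher in line 32. Spots dim on all arrays had a median difference of 0.23 in line 22 and -0.011 in line 32. This floor could account for dim genes only; a real excess of weakly expressed transcripts in line 22 stays open and untested.

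Secondary wall and phenylpropanoid genes were lower in both lines, with a joint median of -0.23 in line 22 and -0.24 in line 32 over 61 genes, but this depends on the setting. The secondary wall median in line 22 was 0.00 after normexp (percentile 6.42), which can be a bound set to 0. With dim probes kept no list was lower than random lists in both lines. Noise of single spots is argued against by further probes, at other spots, of the 10 members that have one: their median was -0.38 in line 22 and -0.82 in line 32, at percentiles 0.22 and 0.00 of further probes of other genes. A first test of further probes had covered 3 of these genes; the medians of the other 7 were -0.34 and -0.50, at percentiles 0.81 and 0.07, with 4 of 7 lower in line 22 and 5 of 7 in line 32. A smaller share of lignifying or vascular tissue in the leaves of both lines may be a cause and cannot be told apart from lower expression: 8 further lignin and xylem genes had a median of -0.20 in line 22, at percentile 1.39, and -0.15 in line 32, at percentile 4.62, inside the central 95%. An effect of the transgene itself stays open and untested, as does a wild-type sample high in these genes, since both lines were set against 1 wild-type array; that would not touch the difference between the lines, 0.34 for secondary wall genes.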
